A study of Mus musculus with 7 samples.

How the data were processed

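Chromosome conformation was measured by 5C (chromosome conformation capture carbon copy) in V6.5 mouse embryonic stem (ES) cells and in neural progenitor cells (NPCs) derived from them. Per the labels' protocols, V6.5 is a male line of mixed 129SvJae and C57BL/6 background. NPCs were made through embryoid bodies grown for 4 days without LIF, 5 to 7 days of selection in serum-free medium and 2 to 4 days of expansion with Fgf2. Cells were fixed in 1% formaldehyde and cut with HindIII, and ligated fragments were read out with forward and reverse primers in an alternating design. The captured regions surround Oct4, Nanog, Sox2, Klf4, Nestin and Olig1-Olig2, with a gene desert as negative control. There were 2 libraries for each of the 2 cell types. The labels number them but do not say that they came from separate cultures, so p-values measure the spread between these libraries, which may be technical. CTCF and the cohesin subunit Smc1 were mapped by ChIP-seq in NPCs, with 1 library each. An input library of NPC chromatin is labelled, and no values of it were used here.

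The 5C table has one line per forward and reverse primer pair. The authors deposited raw read counts per pair and library, which are whole numbers and not normalized. Beside them, the authors deposited a predicted signal per pair and library. The authors also deposited a ratio, which equalled raw reads over the predicted signal at a tolerance of 0.001 except in 7 values, with 0 reads entered as 0.25. A deposited p-value per pair had a lowest value of 1e-05, and a deposited score was its standard normal quantile. The model behind the predicted signal and the p-value is not given in the sources used here. Bowtie is named for the 5C libraries, per the submitters' processing notes. In the table, 4 per-sample columns were not used. The peak lists hold positions on mm9 and a score per peak. MACS is named in the peak names of the deposited lists, and the score behaves as −10 times the log10 of the p-value, with 80 as the lowest. Bowtie and mm9 are named for these libraries per the submitters' processing notes. How the input entered the peak calls is not given in the sources used here, and the depth of the ChIP libraries is unknown.

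The table gives distances between fragments but no chromosome coordinates. Positions along each region were rebuilt from the distances and are given in kb from the lowest-numbered assayed fragment, with a largest misfit of 0.556 bp. The orientation of the regions on their chromosomes is therefore unknown here, and so is the place of each gene within its region.

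Differential contacts were tested per fragment pair with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM factors, cell type as the only term and a mean of at least 10 reads over the 4 libraries. Adjusted p-values are Benjamini-Hochberg values over all pairs tested, with a threshold of 0.05. Fold changes are NPC over ES with their standard error (SE). Against a cell type with 0 reads in both libraries, the fold is a lower bound computed at 3 counts per library. Against 1 to 3 reads, the ratio of depth-scaled reads is given with its exact 95% interval. These intervals and bounds cover counting error only, since PCR copies are not independent molecules. Alternatives were DESeq2 size factors, library totals, a distance-dependent offset, other count filters, the replicate number as a block, DESeq2 1.42.0, limma 3.58.1 on log2(count + 1), and the removal of each library in turn.

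Observed over expected values per library were log2(count + 1) minus a lowess curve of log10 distance (span 0.3) and the median effect of each primer, fitted in 5 rounds per region. A pair was constitutive when it reached 1 or more on this log2 scale in all 4 libraries and was not called by edgeR. ES-specific and NPC-specific pairs reached 1 or more in both libraries of that type and were called higher in it. With a library left out, the remaining library of its type had to reach 1 alone, while the other type still needed both. The class rule was therefore looser in these settings. Decay was the slope of log10(scaled count + 1) on log10 distance from 10 kb to 1 Mb, called the slope of log10 count below. Counts were scaled to the smallest TMM-scaled library size, and pairs with 0 reads were kept. Slopes were compared by a two-sided exact sign-flip test over regions. Regions of the same libraries are not independent replicates. An exact permutation test of 2 against 2 libraries cannot go below p = 0.333.

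The comparisons named above were fixed before the data were examined. Windows and boundaries were added after the data had been seen, together with the rules that name them. In the window test, residuals were averaged per 60 kb by 60 kb window with at least 4 pairs and compared with limma, with a trend on the number of pairs. The boundary contrast at a position is the mean residual of pairs on the same side minus that of pairs spanning the position, within 150 kb on either side, in steps of 10 kb and with at least 20 pairs of each kind. It was compared with limma as well. Neighbouring positions share pairs, so these p-values are not independent and their shared variance estimate is firmer than separate positions would give. With residuals scaled to equal spread, with the authors' ratio and without an NPC library, the same SE served all positions. In these settings the spread at a position did not enter its p-value separately. Also added were a fragment-wide offset, thinning of reads, scaling of residuals to equal spread, the authors' ratio in place of the residuals, summed counts per window in edgeR, a filter on scaled counts, a crossed replicate block, the mean count per distance bin and the removal of the 3 largest pairs. Thinning to equal depth drew reads at random down to the smallest TMM-scaled library size, which left 5007253 and 3844575 reads in ES and 6908488 and 8854945 in NPCs outside the 3 largest pairs. A further thinning therefore equalised the reads outside these pairs, at about 3844575 per library. Both thinned tables were used for the residuals and, in a separate setting, for the count filter and the edgeR calls as well. After the further thinning, pairs with 0 reads made up 17.4% and 13.3% in ES and 30.1% and 39.9% in NPCs.

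Peak overlap was at least 1 bp shared (bedtools 2.31.1), with exact Clopper-Pearson 95% intervals and 1000 circular shifts within chromosomes for chance. Alternatives were 50% of both peaks, a distance of 500 bp and the stronger part of each list (the upper 50% by score). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

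Named pairs were, per region and direction, the 2 called pairs with the largest absolute log2 fold change and separated libraries. Named peaks were the 3 highest-scoring of each list and, added later, the 3 highest-scoring without an overlap. Of the planned tests, 3 were not run: contacts of target gene viewpoints, peaks at contact anchors and peaks at promoters. Each needs fragment coordinates or an mm9 annotation, which were not used here. The planned names that rest on gene starts or on peaks within a region were left out for the same reason.

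The scripts were tested on simulated data. With counts drawn at the fitted dispersion of 0.338 for the 46967 tested pairs, edgeR recovered on average 0.4% of 100 4-fold changes (0% to 2% over 10 simulations) and 32.2% of 100 16-fold changes (17% to 44%), planted in pairs with a mean of at least 30 reads, with 0 to 1 false calls. Most simulated changes of these sizes were therefore missed. The simulated counts were independent between pairs, without effects shared by the pairs of a fragment. Their false calls therefore give no error rate for the real data. Of 8-fold contacts planted in the ES libraries, 94.5% reached the observed over expected threshold, against 1.57% of other pairs. For windows, a planted log2 change of 1 was recovered in 100% of 200 windows with 4 false calls, under a single residual SD of 0.116 for all windows, which makes this recovery optimistic. All 600 planted peak overlaps were found.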

Results

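Contacts between restriction fragments were counted by 5C in 2 libraries of ES cells and 2 of NPCs. The captured regions held 4 loci of transcription factors of pluripotent cells (Oct4, Nanog, Sox2 and Klf4), of which Sox2 is also expressed in neural progenitors. They also held Nestin, an intermediate filament gene of neural progenitors, the Olig1-Olig2 locus of neural lineage transcription factors, and a gene desert as negative control. The table held 86767 pairs of 731 forward and 733 reverse fragments. The Oct4 region spanned 2099 kb, the Nanog region 1134 kb, Olig1-Olig2 1138 kb, Nestin 1086 kb, Sox2 992 kb, Klf4 989 kb and the gene desert 196 kb. Total counts were 10742380 and 8236666 reads in ES replicates 1 and 2, and 15899829 and 42673906 reads in NPC replicates 1 and 2. In all libraries 3 pairs of the Oct4 region took a large part of the reads, 30.3% and 53.3% in ES and 19.7% and 27.2% in NPCs. Pairs with 0 reads made up 11.0% and 13.3% in ES and 18.9% and 22.2% in NPCs. Across pairs, which are not independent replicates, log2 counts correlated at Pearson r = 0.912 between the ES libraries, 0.829 between the NPC libraries and 0.724 to 0.816 between the cell types. Replicates differed by far more than counting noise, with chi-square per degree of freedom of 36.6 in ES and 51.7 in NPCs. The expected split between replicates came from their reads with the 3 largest pairs included. These values therefore also measure those pairs and the library scaling.

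The first comparison asked which contacts differed between ES cells and NPCs. Of 46967 pairs tested, 2300 were higher in NPCs and 1093 were higher in ES cells at an adjusted p under 0.05. The Sox2 region had 405 pairs higher in NPCs and 102 higher in ES cells, Olig1-Olig2 598 and 211, Oct4 611 and 333, Klf4 324 and 144, and Nestin 195 and 155. Nanog went the other way, with 99 pairs higher in NPCs and 141 higher in ES cells. The gene desert, the negative control, had the highest share of called pairs, with 13.7% of its 498 tested pairs higher in NPCs and 1.41% higher in ES cells. Called pairs lay at a median distance of 165 kb when higher in NPCs and 131 kb when higher in ES cells, against 216 kb for all tested pairs. Their median log2 fold changes were 3.29 and −3.33, or 3.27 and −3.33 with pairs at 0 in one cell type set at their bound.

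The excess of pairs higher in NPCs depended on the scaling, the count filter and the depth. With library totals in place of TMM factors, 1092 pairs were higher in NPCs and 1194 in ES cells, the share higher in NPCs fell from 67.8% to 47.8%, the median log2 fold change of all pairs moved from 0.12 to −0.29, and 3 rather than 6 of the 7 regions had more pairs higher in NPCs. A mean of at least 50 reads gave 2549 and 2703 pairs and also 3 regions, and no count filter gave 5936 and 2489. With reads thinned to equal depth edgeR called 3413 and 2085 pairs, and with equal reads outside the 3 largest pairs 3541 and 3321, of which 51.6% were higher in NPCs. DESeq2 called 5084 and 2926 pairs, and limma 3981 and 2548. The counts also rested on single libraries: 233 and 18 pairs were called without ES replicate 1, 46 and 17 without ES replicate 2, 11860 and 11485 without NPC replicate 1, and 3221 and 2260 without NPC replicate 2. In the first pair of these settings the lone ES library was assumed to vary like the NPC libraries, and in the last pair the lone NPC library like the ES libraries.

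Called pairs clustered on single fragments. Fragment FOR121 of the Olig1-Olig2 region took part in 69 called pairs out of 112 tested, all higher in NPCs. Sox2 REV174 did so in 55 of 94 and Klf4 REV310 in 41 of 102, again all higher in NPCs, while Olig1-Olig2 FOR140 had 33 called pairs of 97, all higher in ES cells. These fragments were singled out after their values were seen. Across the 1464 fragments, the 147 with most calls held 40.1% of the ends of called pairs, and 276 fragments had no call. With calls shuffled 1000 times among the tested pairs of each region, these values averaged 23.6% and 77.4 fragments, and the highest were 24.6% and 102. Effects shared by all pairs of a fragment made up 46.5% and 55.4% of the variance within pairs in the ES libraries and 29.3% and 48.2% in the NPC libraries. With a fragment-wide offset, edgeR called 0 pairs in either direction, with 9200 pairs at an unadjusted p under 0.05, while limma with the same offset called 780 pairs higher in NPCs and 133 higher in ES cells. The prior degrees of freedom of edgeR were 4.28 with the offset and 6.14 without it, so that the same ratio of change to SE gave a larger p.

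**Figure D1:**
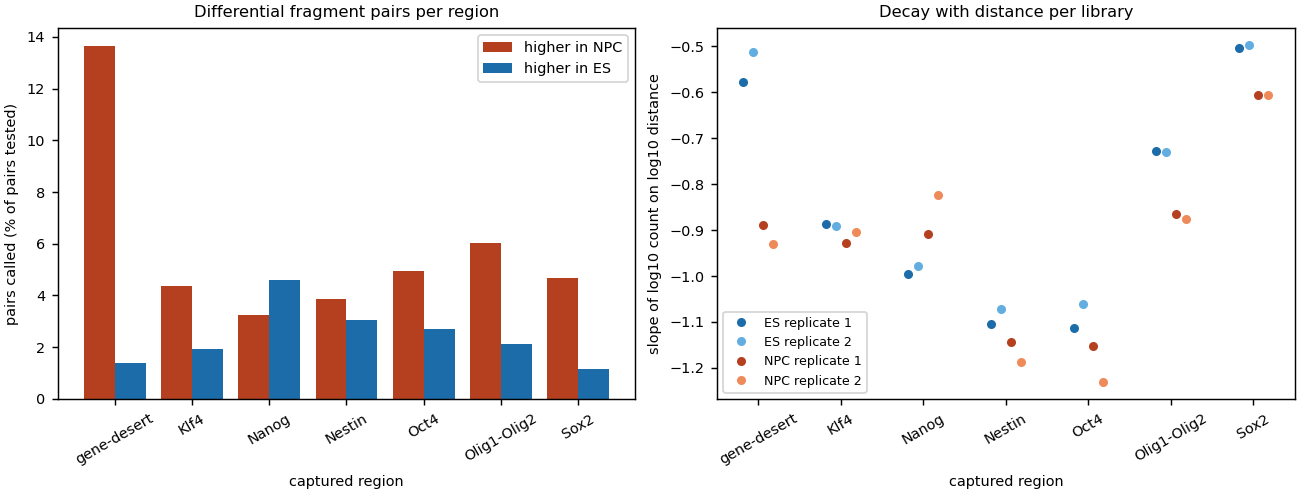
Left, share of tested fragment pairs called by edgeR per captured region (y axis, %), higher in NPCs (red bars) or in ES cells (blue bars); right, slope of log10 count on log10 distance per library (points) and region. The gene desert shows the highest share higher in NPCs (13.7%), and the slopes are steeper in NPCs in 6 of 7 regions.

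Most of the 28 pairs with the largest changes, 2 per region and direction, were close to all-or-none. In 22 of them the lower cell type had 0 reads in both libraries, and in 4 it had 1 to 3 reads, while 2 gene desert pairs had reads in every library. Ranking by fold change favours pairs at 0 in a cell type. Of all called pairs, only 48 of the 2300 higher in NPCs and 16 of the 1093 higher in ES cells had 0 reads in both libraries of the lower cell type. In the Olig1-Olig2 region, FOR127 and REV124, 7.31 kb apart, had 0 and 0 reads in ES and 367 and 2097 in NPCs, at least 159-fold higher (edgeR adjusted p = 0.0225). FOR121 and REV232 of that region, 341 kb apart, had 0 and 0 against 194 and 336 reads, at least 40.1-fold higher. In the Sox2 region, FOR215 and REV174 were 154 kb apart and had 2 and 0 reads in ES against 2296 and 3443 in NPCs, a ratio of 1337 (95% interval 370 to 11040). Sox2 FOR094 and REV116, 59.1 kb apart, had 0 and 0 against 189 and 319 reads, at least 38.6-fold higher. Among pairs higher in ES cells, Klf4 FOR254 and REV025, 643 kb apart, had 41 and 74 reads in ES and 0 and 0 in NPCs, at least 40.9-fold higher in ES. Sox2 FOR171 and REV111, 152 kb apart, had 94 and 26 reads in ES and 2 and 0 in NPCs, a ratio of 129 (34.9 to 1076).

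Other regions showed the same kind of pair. In the Oct4 region, FOR202 and REV096 (66 and 28 reads) and FOR323 and REV446 (41 and 32 reads) were seen in ES cells and had 0 reads in NPCs, at least 29.1-fold and 24.0-fold higher in ES. Oct4 FOR289 and REV396 had 94 and 173 reads in NPCs, and FOR060 and REV449, 1585 kb apart, had 101 and 124, with 0 in ES, at least 20.0-fold and 18.0-fold higher. In the Nestin region, FOR108 and REV160 (88 and 183 reads) and FOR257 and REV081 (101 and 57) were at least 19.9-fold and 14.2-fold higher in NPCs, and FOR080 and REV195 (33 and 13) and FOR013 and REV199 (33 and 8) at least 14.2-fold and 12.1-fold higher in ES. Nanog FOR339 and REV103 (39 and 75 reads) and FOR192 and REV103 (28 and 68) were at least 8.48-fold and 6.90-fold higher in NPCs. Nanog FOR111 and REV204 had 23 and 35 reads in ES against 1 and 0, a ratio of 125 (21.5 to 5002), and FOR175 and REV275 had 38 and 12 against 1 and 0, a ratio of 107 (18.4 to 4323). Klf4 FOR062 and REV222 (46 and 357 reads) and FOR127 and REV133 (68 and 173) were at least 25.3-fold and 17.2-fold higher in NPCs, and Klf4 FOR011 and REV268 (21 and 22) at least 14.5-fold higher in ES. Olig1-Olig2 FOR349 and REV199 (35 and 36) and FOR025 and REV166 (40 and 25) were at least 24.0-fold and 20.9-fold higher in ES, and Sox2 FOR206 and REV084 (28 and 23) at least 16.8-fold. In the gene desert, FOR037 and REV048 (161 and 226 reads) and FOR018 and REV050 (56 and 52) were at least 30.3-fold and 9.01-fold higher in NPCs. There FOR049 and REV019 had 58 and 58 reads in ES against 5 and 4, a log2 fold change of −4.68 ± 0.83 (SE), and FOR065 and REV019 had 50 and 23 against 5 and 3, −4.02 ± 0.97. With the fragment-wide offset 0 of the 28 pairs passed, and the lowest edgeR adjusted p was 0.0631. All 28 kept their direction, and in 25 the fitted log2 fold change stayed within 1 of its value without the offset, although fitted changes against 0 reads are no bounds. Their median SE was 1.37 without and 1.29 with the offset. The change shrank in 3 pairs, from 10.36 ± 0.93 to 6.85 ± 1.07 (SE, log2) for Sox2 FOR215 and REV174, to −2.26 ± 0.56 for gene desert FOR049 and REV019 and to −1.25 ± 0.68 for FOR065 and REV019.

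Larger blocks of contacts were then compared in 60 kb windows. After correction for distance and primer effects, Sox2 lost a block in NPCs. Contacts between 420–480 kb and 480–540 kb stood at 0.70 (log2 observed over expected, mean of 2 libraries) in ES and −0.58 in NPCs. The difference was −1.27 ± 0.09 (SE, limma adjusted p = 0.0250). Contacts of Sox2 360–420 kb with 540–600 kb fell by 1.06 on the log2 scale, from −0.19 to −1.25. In the Olig1-Olig2 region, contacts within 0–60 kb rose from 0.07 to 1.56 and those within 1020–1080 kb fell from 1.05 to −0.14. Within Klf4 720–780 kb, contacts rose from −0.37 to 0.33. Nestin gained contacts within 60–120 kb (−0.28 to 0.69) and lost contacts within 780–840 kb (0.36 to −0.62). Oct4 gained contacts between 1320–1380 kb and 1380–1440 kb (−0.13 to 0.65), and Nanog lost contacts between 600–660 kb and 900–960 kb (0.65 to −0.35). Of 1474 windows, 42 were higher in NPCs and 75 higher in ES cells. The Sox2 region had 7 and 20 of these, Olig1-Olig2 13 and 14, Oct4 8 and 18, Klf4 6 and 9, Nanog 3 and 8 and Nestin 5 and 6, and the gene desert had 0 of 10, with 0 at an unadjusted limma p under 0.05. That 0 did not hold for the control in every setting: 3 of its windows were higher in NPCs with correction for distance alone (limma), 1 was higher in ES without NPC replicate 2 (limma), and edgeR on summed counts called 5 higher in NPCs and 1 higher in ES.

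The number of called windows depended on the setting. With the replicate number as a block and with the crossed block limma called 0 windows. The limma adjusted p of the lost Sox2 contacts was then 0.0769 and 0.0971. Limma called 0 windows without ES replicate 1 (174 at an unadjusted p under 0.05), 0 without ES replicate 2 (186) and 0 with the authors' ratio (532), against 242 higher in NPCs and 549 higher in ES without NPC replicate 1 and 208 and 353 without NPC replicate 2. The 24 named windows had the largest differences per region and direction among called windows with both NPC libraries on the same side of both ES libraries. Leaving out a library could therefore not change their direction. With the authors' ratio, which could, all 24 kept it, at 43.9% to 200% of their size with the residuals. The differences themselves moved less than the calls when a library was left out. Without either ES library they were 79.5% to 120.5% of their size with all libraries, and the calls ended at a median SE of 0.228 against 0.142. The lost Sox2 block was −1.22 and −1.32 without ES replicates 1 and 2 (limma adjusted p = 0.405 and 0.351) and −1.25 with the authors' ratio (0.0675). Windows of 40 kb gave 10 and 10 calls, correction for distance alone gave 245 and 145, scaled residuals 103 and 154, thinning 88 and 131, a pseudocount of 5 gave 90 and 120, and edgeR on summed counts called 269 and 232. Without the correction for primer effects the lost Sox2 block differed by −0.37 (limma adjusted p = 0.162), and on summed counts by −0.19 (edgeR adjusted p = 0.595). Of the 24 named windows, 21 kept their direction in each of these settings. Limma called 17 of them with distance alone, and edgeR called 14 on summed counts.

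**Figure D2:**
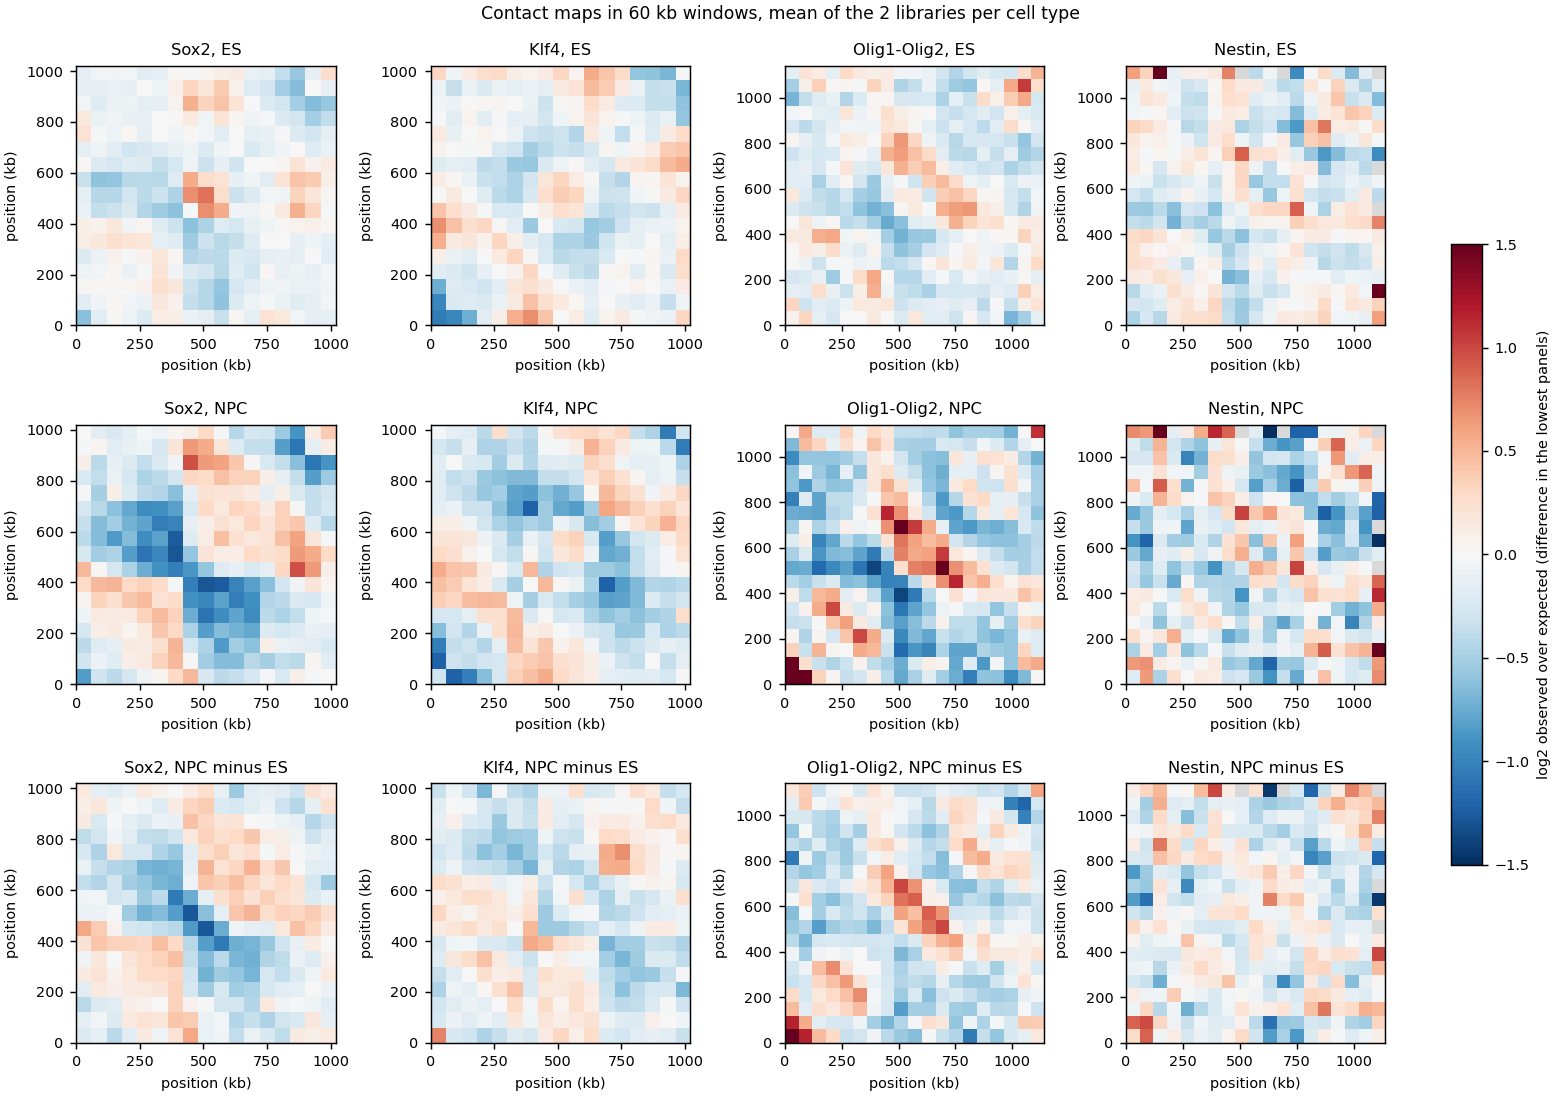
Mean log2 observed over expected per 60 kb window (color, −1.5 to 1.5) for Sox2, Klf4, Olig1-Olig2 and Nestin, with position in kb on both axes; upper maps show ES cells, middle maps NPCs and lower maps NPC minus ES, each the mean of 2 libraries. In Sox2 the window joining 420–480 kb and 480–540 kb goes from 0.70 in ES to −0.58 in NPCs.

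Boundaries between neighbouring blocks were measured as the mean contact of pairs on the same side of a position minus that of pairs spanning it. The strongest Sox2 boundary in NPCs, at 430 kb, stood at 0.66 in ES and 1.25 in NPCs. On its flank at 470 kb the contrast rose from −0.09 to 0.68, and at 590 kb a boundary of ES cells fell from 0.47 to 0.02. In Olig1-Olig2 the contrast at 720 kb rose from −0.11 to 0.55, beside the strongest NPC boundary at 740 kb (0.16 in ES and 0.82 in NPCs). At 590 kb it fell from −0.27 to −0.94, so contacts across that position grew relative to those on either side. Oct4 lost a boundary at 1100 kb, from 0.47 to −0.39, and rose at 320 kb from −0.31 to 0.24. In the Nanog region the boundary at 660 kb was stronger in NPCs, at 1.22 against 0.56, and the contrast at 200 kb fell from −0.06 to −0.39. With residuals scaled to equal spread, the contrast at 660 kb was 1.02 in NPCs and 0.76 in ES. The gain at 640 kb, the strongest Nanog position in NPCs, went from 0.54 to 0.11 in that setting. At 620 kb, the strongest in ES, it went from 0.34 to −0.15. The Klf4 boundary at 630 kb stood at 0.30 in ES and 0.93 in NPCs, and the one at 400 kb fell from 0.43 to 0.07. Nestin rose at 200 kb from −0.26 to 0.29 and fell at 540 kb from −0.32 to −0.59. The strongest Nestin boundary, at 810 kb, stood at 0.78 ± 0.06 (SD, n = 2) in ES and 0.90 ± 0.25 (SD, n = 2) in NPCs, a difference within the spread between replicates (limma adjusted p = 0.355). Its direction depended on the setting, with −0.32 after scaling to equal spread (limma adjusted p = 3.03e-06) and 0.31 with the authors' ratio (0.00979). These fits used the same SE at every position (0.0631 and 0.106), so these p-values do not measure the spread at 810 kb. The difference was 0.29 without NPC replicate 1 and −0.06 without NPC replicate 2.

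Across the 6 large regions, 218 of 626 overlapping positions had a stronger contrast in NPCs and 126 a weaker one (limma). The counts of weaker positions were 77 without ES replicate 1, 64 without ES replicate 2 and 32 with the authors' ratio. The largest gain and loss of each region were named among positions with both NPC libraries on the same side of both ES libraries. Leaving out a library or adding the replicate block could therefore not reverse them. Their limma adjusted p-values do not allow for this choice on the same data. They ran from 9.21e-05 to 0.00282 for the 12 named positions. Of these, 10 were called in all 10 other settings. Klf4 at 400 kb was lost with the authors' ratio (limma adjusted p = 0.168), and Nestin at 540 kb with the authors' ratio and with residuals scaled to equal spread (highest limma adjusted p 0.392). Sizes changed as well. With scaled residuals the gain fell from 0.66 to 0.26 at Nanog 660 kb, from 0.62 to 0.37 at Klf4 630 kb and from 0.65 to 0.60 at Olig1-Olig2 720 kb. It rose from 0.55 to 0.62 at Oct4 320 kb and from 0.55 to 0.59 at Nestin 200 kb. With the authors' ratio the Nanog and Klf4 gains were 0.90 and 0.92. Boundary profiles correlated across positions at r = 0.974 to 0.991 between replicates and at 0.678 to 0.894 between cell types.

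**Figure D3:**
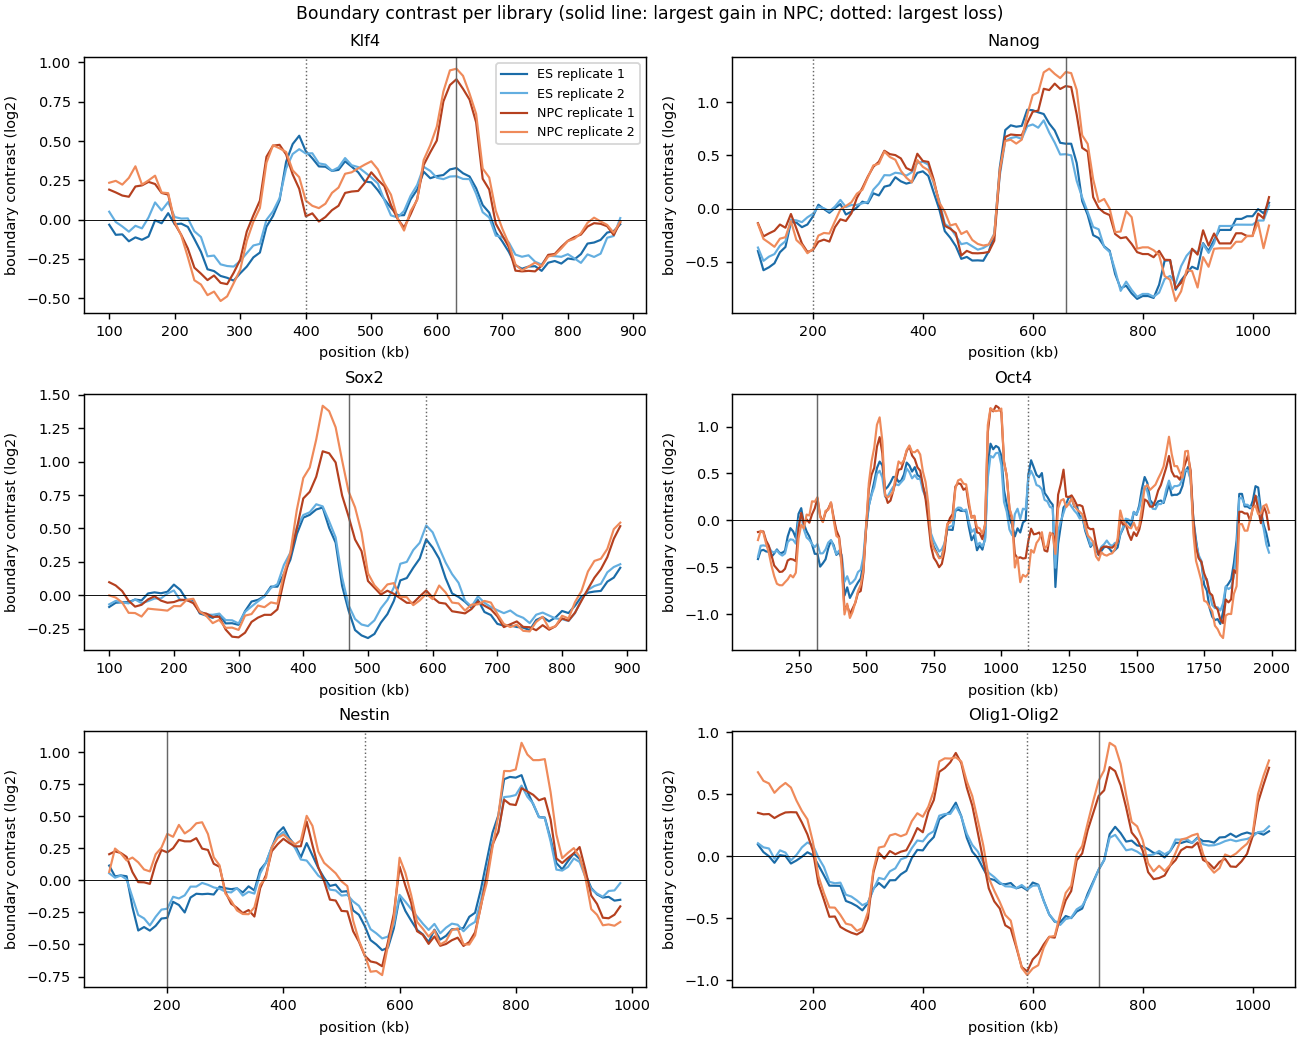
Boundary contrast (log2, y axis) along each region (position in kb, x axis) for the ES libraries (blue lines) and the NPC libraries (red and orange lines); solid vertical lines mark the largest gain in NPCs and dotted lines the largest loss. In Sox2 the ES lines lie near −0.09 at 470 kb and the NPC lines near 0.68, while at 590 kb the ES lines lie near 0.47 and the NPC lines near 0.02.

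Contacts stronger than distance and primer effects predict were then sorted into constitutive and cell-type-specific pairs. There were 1003 constitutive, 1041 NPC-specific and 136 ES-specific pairs. Constitutive pairs were not called by edgeR, which missed most simulated 4-fold and 16-fold changes. The class therefore does not show that these contacts were equal in the cell types. Oct4 had most constitutive pairs, 498, with 378 NPC-specific and 36 ES-specific. Olig1-Olig2 had 156 constitutive, 214 NPC-specific and 19 ES-specific pairs, Sox2 61, 149 and 18, Klf4 83, 117 and 16, Nestin 91, 114 and 28, Nanog 112, 62 and 19, and the gene desert 2, 7 and 0. In all, 1494 pairs were over the threshold in all 4 libraries, against 282 if the cell types were independent. NPC-specific pairs were on average 149 kb longer than ES-specific pairs, longer in 5 of 6 regions with both, and this did not pass an exact two-sided sign-flip test (p = 0.0625, smallest possible 0.0313). The excess of NPC-specific pairs went with a wider spread of residuals in the NPC libraries, 1.37 and 1.70 (SD, log2) against 0.948 and 0.943 in ES. Scaled to equal spread, the classes held 1156 constitutive, 865 NPC-specific and 248 ES-specific pairs, and correction for distance alone gave 12305, 2072 and 788. With a library left out, the remaining library of its type had to reach the threshold alone, so the counts that follow are not comparable with those above. Leaving out single libraries gave 1485 constitutive, 159 NPC-specific and 13 ES-specific pairs without ES replicate 1, 1671, 40 and 13 without ES replicate 2, 839, 5896 and 609 without NPC replicate 1, and 1241, 1979 and 170 without NPC replicate 2.

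Contact counts fell with distance in every region and library. The slope of log10 count on log10 distance was steeper in NPCs in the gene desert (−0.910 against −0.546), Olig1-Olig2 (−0.870 against −0.729), Sox2 (−0.606 against −0.500), Oct4 (−1.19 against −1.09), Nestin (−1.17 against −1.09) and Klf4 (−0.916 against −0.889). Nanog was shallower in NPCs, at −0.867 against −0.987. The mean difference over the 7 regions was −0.100 ± 0.145 (SD), which did not pass an exact two-sided sign-flip test (p = 0.109, smallest possible 0.0156). With the mean count per distance bin in place of single pairs, the difference was −0.136 in mean and the exact test gave p = 0.0156, with 7 of 7 regions steeper in NPCs. In that setting Nestin differed by −0.00159 and Nanog by −0.0139, far less than the spread between the ES replicates (SD 0.113 and 0.0947, n = 2), so the 7 of 7 and the smallest possible exact p rest on the signs of these small differences. Bin means also weigh pairs with many reads, such as Oct4 FOR406 and REV190, 856 kb apart. That pair took 6.95% and 18.3% of ES reads and 1.93% and 2.80% of NPC reads. The Oct4 difference was −0.327 over bins against −0.105 with single pairs, and the part of that pair in it was not tested.

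The authors' deposited p-values mark pairs above the authors' own model in each library. There were 4788 and 5125 pairs under 0.05 in ES replicates 1 and 2, and 3920 and 3904 in NPC replicates 1 and 2. These were 5.52%, 5.91%, 4.52% and 4.50% of all pairs, close to the 5% that the threshold gives by chance. Of these, 1467 were shared by both ES libraries, against 283 if independent, and 1242 by both NPC libraries, against 176. In the Oct4 region 531 pairs were shared in ES and 524 in NPCs, in Sox2 166 and 146, and in Nanog 159 and 71. Over all regions 325 pairs were under 0.05 in all 4 libraries, against 21.0 if the cell types were independent.

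The ChIP-seq lists addressed where the DNA-binding protein CTCF and cohesin lie together in NPCs. Of 37991 Smc1 peaks, 29161 overlapped a CTCF peak, 76.8% (95% interval 76.3 to 77.2). Of 42893 CTCF peaks, 29066 overlapped a Smc1 peak, 67.8% (67.3 to 68.2). Shifted lists gave 1.5% and 1.32% on average, and none of 1000 shifts reached the observed overlap (permutation p = 0.000999, the smallest possible). Scores are the authors' and rank peaks within a list. Shared Smc1 peaks had a median score of 318 and the 8830 Smc1 peaks without CTCF 113. For CTCF, the medians were 402 for shared peaks and 129 for the 13827 without Smc1. Overlap rose with score: of 10 equal score groups, the lowest overlapped in 39.0% (Smc1) and 22.3% (CTCF), and the highest in 99.8% and 99.0%. Without replicates, there was no test between conditions.

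**Figure D4:**
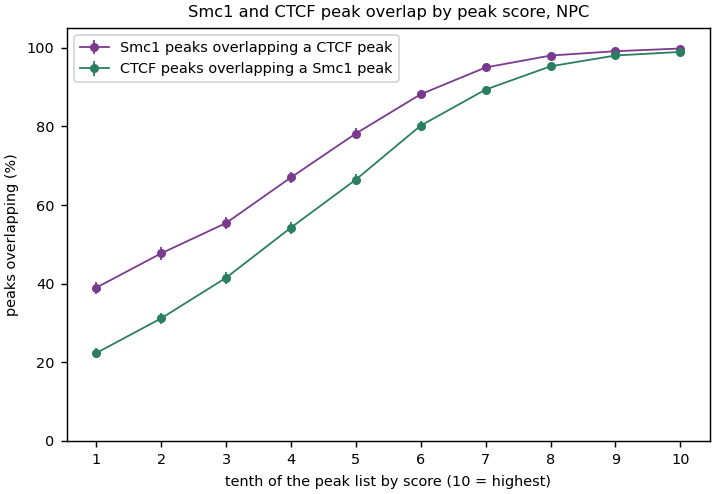
Percentage of peaks overlapping a peak of the other protein (y axis) in 10 equal groups by score (x axis, 10 is the highest score), for Smc1 peaks (purple) and CTCF peaks (green) in NPCs, with exact 95% intervals. Smc1 goes from 39.0% to 99.8% and CTCF from 22.3% to 99.0%.

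All of the highest-scoring named peaks of both lists were shared. For Smc1 these were chromosome 9, 42752350–42753204 (mm9, score 3119), and chromosome 15, 101896099–101896598, and chromosome 7, 35456904–35457391, which are among 4 peaks tied at a score of 3100. For CTCF they were chromosome 2, 39228474–39229151 (score 3212), chromosome 11, 62570072–62570858 (3201), and chromosome 9, 72378009–72378489 (3196). The highest Smc1 peaks without CTCF were chromosome 11, 107645335–107646039 (1503), chromosome 3, 21834319–21835400 (1403), and chromosome 13, 5869596–5871355 (1289). The highest CTCF peaks without Smc1 were chromosome 2, 164215188–164215885 (1621), chromosome 14, 51405047–51405474 (1427), and chromosome 8, 98412036–98412707 (1348). No annotation of mm9 was used, so the genes at these positions were not analysed here.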

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

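All window and boundary settings were chosen after seeing the data, as were, for the other results, the fragment-wide offset, the filter on scaled counts, the crossed block, the distance bins, both kinds of thinning, the authors' ratio, the scaled residuals and the removal of the 3 largest pairs; the other settings were planned. Causes of the changes given here were not tested. Pairs higher in NPCs and in ES cells (2300 and 1093) became 1092 and 1194 with library totals, 5936 and 2489 without a count filter, 2549 and 2703 at a mean of at least 50, 3413 and 2085 with reads thinned to equal depth, 3541 and 3321 with equal reads outside the 3 largest pairs, 5084 and 2926 with DESeq2 (5464 pairs without an adjusted p) and 3981 and 2548 with limma. With edgeR and a fragment-wide offset they became 0 and 0 (9200 at an unadjusted p under 0.05), and with limma and that offset 780 and 133. DESeq2 size factors, the distance offset, the filter on scaled counts and the removal of the 3 largest pairs kept both counts within 1.5 times. Without single libraries they ranged from 46 to 11860 and from 17 to 11485. Regions with more pairs higher in NPCs went from 6 to 3 with library totals and at a mean of 50, to 4 with equal reads outside the 3 largest pairs, to 0 with edgeR and the fragment-wide offset, which called 0 pairs, and to 7 of 7 with limma and that offset. Replicate numbers are shared by the cell types, but deviations of same-numbered libraries correlated at r = −0.155, so the numbers were not taken to pair the libraries. With the replicate block 2917 and 1664 pairs were called, and with the crossed pairing 3573 and 1604. For windows (42 and 75), both blocks gave 0 and 0 (limma, 441 and 442 at an unadjusted p under 0.05), with the 24 named differences unchanged by construction, 1 residual degree of freedom fewer and adjusted p-values of 0.0769 to 0.105. The authors' ratio also gave 0 and 0 (532), and all 24 kept their direction. Windows of 40 kb gave 10 and 10, distance alone 245 and 145, a pseudocount of 5 90 and 120, thinning to equal depth 88 and 131, thinning to equal reads outside the 3 largest pairs 147 and 161, scaling 103 and 154 and edgeR on summed counts 269 and 232, and single libraries left out 0 to 242 and 0 to 549. Named windows reversed without passing in 6 cases: Klf4 within 0–60 kb (−0.31 with distance alone, −0.32 on summed counts, against 0.75), Klf4 300–360 kb with 720–780 kb (0.19 and 0.31, against −0.69), Nestin 240–300 kb with 660–720 kb (0.42 with distance alone, against −0.95) and Oct4 420–480 kb with 1380–1440 kb (0.55 on summed counts, against −1.09). Boundary positions stronger in NPCs (218) stayed within 1.5 times in every setting run, from 157 to 262, and weaker positions (126) were 32 with the authors' ratio and 64 to 148 without single libraries. The replicate block gave 218 and 124 boundary positions. Of 120 checks of the 12 named boundaries, 117 kept the call, and of 487 checks of the named pairs, 396 did. Of 312 checks of the named windows, 168 kept the call, 138 lost it and 6 reversed. Constitutive, ES-specific and NPC-specific pairs (1003, 136 and 1041) were 3315, 397 and 1447 at a threshold of 0.5, 317, 58 and 700 at 1.5, and 12305, 788 and 2072 with distance alone. ES-specific pairs were 206 with the replicate block, 248 with scaled residuals and 250 with both calls and residuals at equal depth; with both at equal reads outside the 3 largest pairs, 346 were ES-specific and 1730 NPC-specific. Leaving out single libraries gave 839 to 1671 constitutive, 13 to 609 ES-specific and 40 to 5896 NPC-specific pairs. The decay difference of −0.100 (exact p = 0.109) became −0.136 over distance bins (exact p = 0.0156, the smallest possible), ranged from −0.0878 to −0.112 without single libraries and kept its sign in all settings. The overlap of Smc1 peaks (76.8%) was 72.0% at 50% of both peaks, 78.0% within 500 bp and 82.0% for the stronger part of each list. For CTCF peaks (67.8%) it was 63.8%, 68.8% and 72.5%. At the fitted spread between libraries, the pair test recovered 17% to 44% of simulated 16-fold changes in pairs with a mean of at least 30 reads; what depth alone limits was not simulated. Planned settings of 3 tests (target gene viewpoints, peaks at contact anchors and peaks at promoters) were not run, since these tests were not run.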

Other observations

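Of the tests in this part, the neighbour correlation of fragments, their correlation at equal depth and the class ratio after scaling were set before their values were seen; all others were chosen after the result was seen. Peaks of one protein without the other lay closer to it than shifted lists did. Of Smc1 peaks without CTCF, 41.9% lay within 10 kb of a CTCF peak, against 24.1% for shifted lists, and of CTCF peaks without Smc1, 41.4% lay within 10 kb of a Smc1 peak, against 22.5%. Overlap differed between chromosomes. Smc1 peaks overlapped CTCF in 71.0% of cases on chromosome 8 and 81.1% on chromosome 11, the lowest and highest autosomes, and in 82.2% on the X chromosome. CTCF peaks overlapped Smc1 in 60.8% on chromosome 5, 71.9% on chromosome 16 and 73.5% on the X chromosome. The 1 Mb stretch with most Smc1 peaks lacking CTCF was chromosome 8, 129000001–130000000 (mm9), with 31 against a median of 3. For CTCF peaks lacking Smc1 it was chromosome 5, 150000001–151000000, with 39 against a median of 5.

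Changed pairs shared single fragments, such as Olig1-Olig2 FOR121, Sox2 REV174 and Klf4 REV310. The fragment medians kept a Pearson r of 0.995 with reads thinned to equal depth and 0.990 with equal reads outside the 3 largest pairs. In both, 10 of the 10 fragments with most calls kept their shift. Thinned reads are drawn from the same reads, so this was likely whatever the source and does not decide on depth. Without the 3 largest pairs 3850 pairs were called against 3393. A total of calls does not measure the sharing of fragments, so this does not decide on the 3 largest pairs. A candidate explanation is recovery of single fragments (cutting, primer or ligation yield) that differed between the libraries of the cell types: median shifts of neighbouring fragments within 10 kb correlated at r = 0.0406 (bootstrap 95% interval −0.0256 to 0.0998), and 57 of 1000 shifted orders gave as much. A change of chromatin at single fragments, which the design could also bring, stays open and untested.

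The lost Sox2 block between 420–480 kb and 480–540 kb was −1.27 (NPC minus ES, log2). Residuals scaled to equal spread gave −1.44, which cannot decide on the wider spread of NPC values. Scaling multiplies each library by a constant, and both ES values were positive and both NPC values negative. The block was −1.19 with reads thinned to equal depth and −1.11 with equal reads outside the 3 largest pairs, so unequal read numbers alone did not produce its size. Thinned reads are drawn from the same reads, so other differences between the libraries are not addressed by this. The block shrank to −0.37 with correction for distance alone, so the correction for primer effects may account for much of its size. The boundary contrasts at 470 kb and 590 kb were called in all 10 other settings, distance alone included. Both contrasts contain pairs of the block itself and were named from the same data, so they are no separate evidence for it. That the block moved with the cell type remains a hypothesis found and tested on the same data.

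NPC-specific pairs outnumbered ES-specific pairs by a ratio of 7.65, against 2.10 among all called pairs. Ratios without single libraries are not compared with it, since the remaining library of a type then had to reach the threshold alone. With correction for distance alone the ratio was 2.63, a fall whose cause was not tested. The tables argue against depth as the whole source: with both the edgeR calls and the residuals from reads thinned to equal depth the ratio was 6.22, against 1.64 among called pairs, and with equal reads outside the 3 largest pairs 5.00, against 1.07. Scaled to equal spread it was 3.49, between the bounds set for and against the wider spread of NPC values as the source, so spread and cell type cannot be told apart here, as both NPC libraries had the wider spread.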
